A study of Galaxea fascicularis with 9 samples.

How the data were processed

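Microarray signals of microbial functional genes were taken from DNA of coral tissue in 9 samples, 3 in each of 3 seawater treatments. Per the labels' protocols, genomic DNA of each microcolony was extracted with a commercial kit, labelled with Cy5 and hybridised to a functional gene array. The deposited values are intensity values of 1 colour on a linear scale, with a blank where a probe has no value. The scanner, the image software, the rule behind the blanks and any normalization are not given in the sources used here. The deposited table carries the title of raw data, yet its array totals agree within 1.11-fold although the number of detected probes differs 1.68-fold and the mean detected signal 1.58-fold. The table has 58794 lines, of which 1 names no gene and was left out. It lists 372 gene names, and 29692 probes had no value on any array. A blank was read as undetected.

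Groups were taken from the pH in the sample labels. The design, the tests, the gene lists and most alternatives were fixed before the data were examined. The fixed rule was to scale each array by its mean over detected probes if blanks were present, but to apply no further scaling where the totals or the means were already equal. The totals were judged equal, so values were used as deposited, and mean scaling, total scaling, a common floor, a common detection limit and other numbers of brightest probes were added as alternatives after the data had been seen. Because the means were not equal, this reading of the rule is a choice. No depth can be given for arrays; their number limits the precision, and the lowest signals per array, from 97.2 to 378, show that the limit of detection differed between them.

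A probe was tested if it was detected on at least 2 arrays of 1 group, which left 23038 probes with 23.7% of their values undetected. A gene family is the set of probes with one gene name, and its value is the log2 of the sum of their signals, with undetected values as 0. Families with at least 5 tested probes were tested, 259 in all, and the other 113 were not. Single probes were tested on the log2 scale, with an undetected value set to the lowest signal of its array. Each comparison was fitted in limma 3.58.1 (R 4.3.3) with all 9 arrays, an intensity trend of the prior variance and two-sided moderated tests, and a Benjamini-Hochberg adjusted p under 0.05 was a call. A moderated F test over the 3 groups and a slope with pH were fitted likewise. Signals were also summed by the gene category, domain and phylum that the deposited table gives for each probe, and tested in limma and by exact permutation.

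Gene sets were 37 lists of families fixed in advance, of which 26 had tested families and 11 had no family in the table, among them the lists of heat shock, oxidative stress and acid homeostasis. The 80 subcategories of the table with at least 10 tested probes were a further collection. Sets were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry, all from limma. Richness, the Shannon and inverse Simpson indices and the share of the 100 brightest probes were compared by exact two-sided permutation tests, with 10 distinct regroupings per pair and 280 over 3 groups. The test over 3 groups was planned for richness and was added for the indices and the share. Community structure was tested by PERMANOVA on Bray-Curtis distances in vegan 2.7.1 with every regrouping counted.

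The text names, for each comparison, the 12 families with the smallest p, whether or not they passed, and in the comparisons against pH 8.15 also nifH, amoA, narG, nirK, nirS, nosZ, ureC, dsrA, dsrB, rubisco, mcrA, pmoA, ppx, ppk, phytase, dnaK, groEL, katA and ahpC where tested. Lists past the threshold are named too. Other families, lists, taxa and single probes that the text names were chosen after their values were seen. Phyla and genera are those of the organisms the probes were designed on, since the array does not show which organism carried the DNA.

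The procedure was tested on simulated data for pH 8.45 against pH 8.15. Of 20 families changed by 1 on the log2 scale 13 were called, of 20 changed by 2 there were 19, and of 219 unchanged families 1 was called. Of 100 probes changed by 2 there were 11 called, of 100 changed by 4 there were 71, and of 22838 unchanged probes 2 were called. With no change simulated, 0 families and 0 probes were called. In a simulation with the nitrogen fixation list raised, camera called that list and 0 of the other 25. The simulated noise was independent between families and between probes, without shifts shared by the probes of an array. These counts therefore do not give the rate of false calls where such shifts are present.

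Alternatives were quantile normalization, median scaling over the probes detected on all 9 arrays, other detection filters, undetected values left missing, a stricter detection limit, the mean of probe log2 values as the family value, other limma settings, the replicate number as a block, other distances and leaving out each array in turn. Slide or scan batches are not given in the sources used here, and no background columns were available for a background correction.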

Results

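Functional genes of the microbial community in coral tissue were measured with 9 functional gene microarrays, 3 for each of 3 seawater treatments. Colonies of the reef coral *Galaxea fascicularis* had been kept for 10 days at 25 °C in acidified seawater at pH 7.85, in ambient seawater at pH 8.15 or in alkalinized seawater at pH 8.45. Dissolved inorganic carbon was 2176, 2030 and 1833 µmol per kg in these treatments. Each array carried genomic DNA from 1 microcolony, taken from 1 of 3 replicate tanks per treatment. A probe signal therefore measures the abundance of a gene variant in DNA and not its expression. The probes belong to gene families that carry out steps of carbon, nitrogen, sulfur and phosphorus cycling, degrade organic compounds, or confer resistance to metals and antibiotics. Of 58793 probes with a gene name, 29101 had a value on at least 1 array and 8898 had a value on all 9. The total signal per array lay between 45548670 and 50586380 intensity units, and the highest total exceeded the lowest 1.11-fold. A total of 259 gene families and 23038 probes were tested. Family names are given in their usual capitalisation.

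The breadth and evenness of the gene pool were compared first, which asks whether seawater pH altered how many functional genes were detected and how evenly they shared the signal. Detected probes numbered 17711 ± 1974 (SD, n = 3) at pH 7.85, 20485 ± 3990 at pH 8.15 and 17565 ± 3255 at pH 8.45, with an exact two-sided permutation p of 0.486 over the 3 groups. Above one detection limit common to all arrays, the numbers were 16570.0 ± 880, 17703 ± 1777 and 15047 ± 1413 (exact permutation p 0.125). The Shannon index of functional genes was 8.71 ± 0.07 at pH 7.85, 8.90 ± 0.13 at pH 8.15 and 8.38 ± 0.20 at pH 8.45. It differed among the 3 groups (exact two-sided permutation p 0.00714), although not after quantile normalization (exact p 0.454). That normalization gives the probes detected on all 9 arrays one signal distribution and adjusts the other probes along with them. The inverse Simpson index was 1569 ± 125, 2098 ± 526 and 1198 ± 193 in the same order (exact two-sided permutation p 0.0429). With 1 array left out in turn its exact p lay between 0.00357 and 0.114, and it was under 0.05 only without pH 8.15 replicate 3. The 100 brightest probes of each array held 18.3% ± 2.2, 15.4% ± 1.7 and 22.8% ± 2.6 of the total signal (exact two-sided permutation p 0.0107). Between pH 8.45 and pH 8.15 the arrays did not overlap in either index or in this percentage, with the smallest exact p that 3 arrays against 3 allow, 0.1. The same held between pH 7.85 and pH 8.45, with an exact p of 0.1 for each. Between pH 7.85 and pH 8.15 the exact p was 0.2 for the Shannon index, 0.3 for the inverse Simpson index and 0.2 for the percentage.

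**Figure D1:**
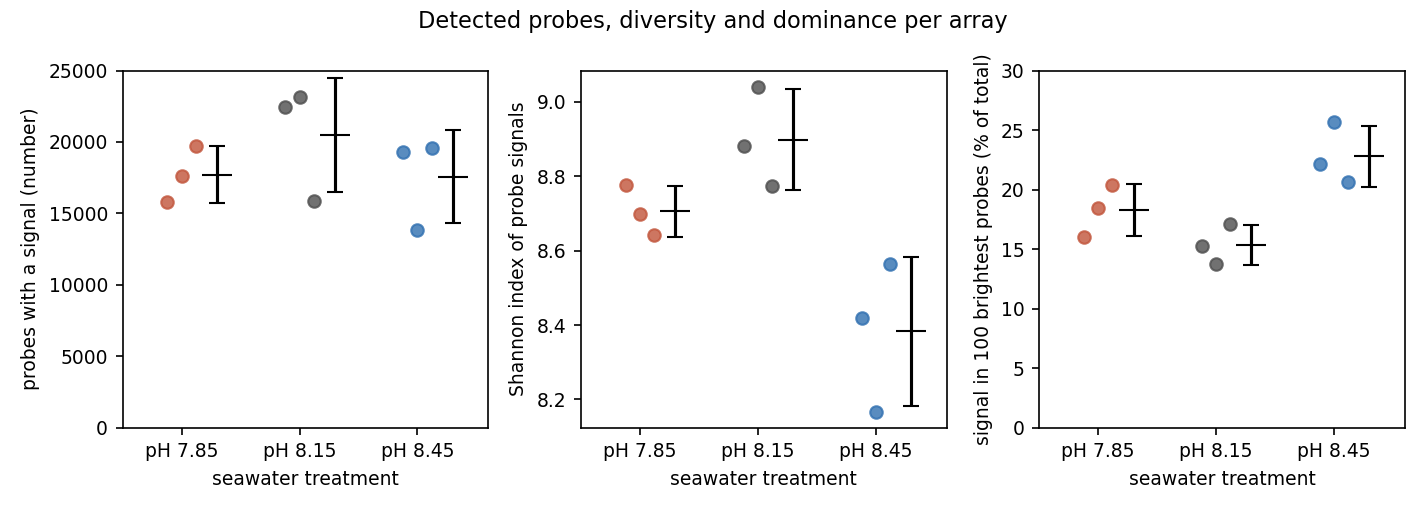
Detected probes (number), Shannon index and the percentage of total signal in the 100 brightest probes for each array (points), with the mean and SD of the 3 arrays of each treatment beside them. The lowest pH 8.45 array held 20.6% of its signal in the 100 brightest probes, above the highest pH 8.15 array at 17.1%.

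Functional community structure was compared through Bray-Curtis distances between the probe profiles. The treatments accounted for 31.9% of the variation, with an exact permutation p of 0.0821 over 280 regroupings of the 9 arrays. Random groupings of so few arrays account for a share of the variation too, which the exact p allows for. Between pairs of treatments the share was 34.2% for pH 8.45 against pH 8.15, 25.7% for pH 7.85 against pH 8.45 and 15.5% for pH 7.85 against pH 8.15. The exact p was 0.1, 0.1 and 0.9 in that order, and 0.1 is the smallest that 10 regroupings allow. The median distance was 0.355 within treatments and 0.371 between them. Correlations of log2 signals between arrays were also alike, with a median of 0.732 within and 0.752 between treatments.

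**Figure D2:**
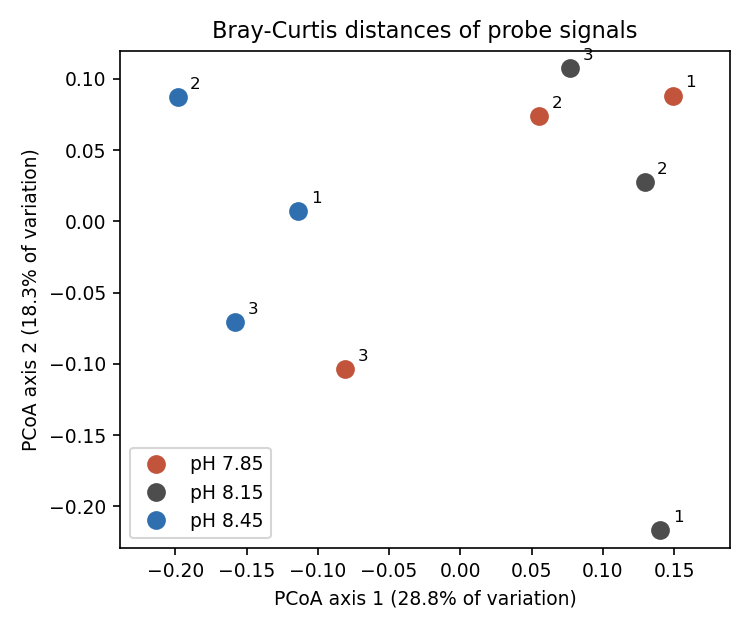
Principal coordinates of the Bray-Curtis distances between the 9 arrays, with axis 1 (28.8% of the variation) against axis 2 (18.3%), colours for treatments and replicate numbers beside the points. The 3 arrays of pH 8.45 have the lowest positions on axis 1, and pH 7.85 replicate 3 lies nearest to them.

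Acidified seawater was compared with ambient seawater to ask which microbial functions differ when carbon dioxide is added. Inulinase, which cleaves the storage fructan inulin, and xylXY, the oxygenase that opens the breakdown of aromatic carboxylic acids, had lower mean signal at pH 7.85. Beta-lactamase, which inactivates beta-lactam antibiotics, had higher mean signal, as did the fungal exopolygalacturonase and chitin deacetylase families that act on pectin and chitin. None of these families passed. The inulinase difference was -1.04 on the log2 scale (SE 0.32), the xylXY difference was -0.92 (SE 0.32) and the beta-lactamase difference was 0.50 (SE 0.19), each without overlap between the 3 and 3 arrays and each with a limma adjusted p of 0.998. Limma called 0 of the 259 families, 3 had an unadjusted p under 0.05 where 12.95 would be expected by chance, and 0 of the 23038 probes were called, with 781 at an unadjusted p under 0.05. Arrays of the treatments did not overlap in 17 families (6.56%, against 10% by chance).

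The remaining families with the smallest p in this comparison also did not pass. The signal of alkK, of endoglucanase (cellulose), of quinoline degradation, of acetylglucosaminidase (chitin), of glx (lignin), of exopolygalacturonase and of chitin deacetylase was higher by 0.26 to 0.69 on the log2 scale, and that of hsp90 from Fornicata and of trzA (triazine herbicides) lower, at -0.76 and -0.64. These signs held under every scaling, while leaving out 1 array brought glx down to 0.16, alkK to 0.17, endoglucanase to 0.21 and quinoline degradation to 0.31, and exopolygalacturonase up to 1.05. As a mean of probe log2 values, endoglucanase (-0.03), acetylglucosaminidase (-0.06), glx (-0.08) and chitin deacetylase (-0.09) turned negative. Families of the nitrogen cycle lay close to 0, with a log2 difference of 0.04 for nifH, the nitrogenase gene, 0.06 for narG, -0.02 for nirK, -0.01 for nirS and -0.09 for nosZ, the steps of denitrification. The ammonia oxidation gene amoA differed by 0.27, but by -0.02 as a mean of probe log2 values, and the urease gene ureC by -0.12. In the sulfur and carbon cycles the differences were 0.10 for dsrA, -0.03 for dsrB, -0.25 for the methanogenesis gene mcrA, 0.04 for the methane oxidation gene pmoA and 0.04 for rubisco. In the phosphorus cycle they were -0.06 for ppk, -0.05 for ppx and -0.00 for phytase. Mean scaling turned the small positive differences of nifH, narG, dsrA, pmoA and rubisco negative, quantile normalization did so for nifH, and median scaling turned nirS and phytase positive. Leaving out 1 array changed the sign of nifH, nirK, nirS, dsrB, pmoA, rubisco, ppx and phytase, while amoA ran from 0.17 to 0.38, mcrA from -0.40 to -0.15 and ureC from -0.25 to -0.0052. The heat shock and oxidative stress families dnaK, groEL, katA and ahpC were not among the tested families.

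Among the fixed gene lists, all 10 tested families of aromatic carbon degradation had lower signal at pH 7.85 with deposited values, and 9 of the 10 after median scaling. Of all 259 families, 160 had lower signal with deposited values. The log2 differences of the 10 aromatic families ran from -0.31 to -0.00 with a median of -0.18, and 0 rose, 0 fell and 10 did not pass. The 12 carbon fixation families split into 3 with higher and 9 with lower signal, the 5 denitrification families into 2 and 3, and the 7 sulfur oxidation families into 4 and 3, which after mean scaling were 1 and 6. Each list was adjusted by itself in every comparison, with no adjustment across the 26 lists. The list of other antibiotic resistance families has only 2 tested families. From it beta-lactamase passed when adjusted over the list alone (limma adjusted p 0.0370), as the only family of any list in this comparison. Its summed signal was higher by log2 0.50 as deposited, 0.24 after quantile normalization, 0.30 after mean scaling and 0.52 after median scaling. However, 44 of its 78 probes had lower signal and its mean of probe log2 values differed by -0.02. In this comparison 65 of the 259 families had a higher sum and a lower mean of log2 values. Of 26 lists, camera called 0, with 0 at an unadjusted p under 0.05, and fry likewise called 0 with 0 at an unadjusted p under 0.05. The list of other antibiotic resistance families was the only one whose median and mean over probes differed in sign. Signal summed by gene category and by taxon showed 0 limma calls, with 1 category and 1 taxon at an unadjusted p under 0.05. The category was virulence genes, whose summed signal differed by 0.25 on the log2 scale (limma adjusted p 0.131). Its share of the signal, not tested itself, was 2.39% ± 0.32 at pH 7.85 and 2.01% ± 0.10 at pH 8.15.

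Alkalinized seawater was compared with ambient seawater to ask which functions differ when carbon dioxide is removed. One family passed: the signal of xylXY, the dioxygenase that starts the breakdown of aromatic carboxylic acids such as toluate and benzoate, fell. Families that fix nitrogen (nifH), take part in thiosulfate oxidation (SoxV), degrade pectin (pme and pme_Cdeg), hemicellulose (ara) and fungal chitin (chitin deacetylase) had higher mean signal at pH 8.45 and did not pass. The xylL family, which acts on the product of xylXY in the same pathway, had higher mean signal as well. Inulinase, the fungal glucose oxidase and pcpB, which oxidises pentachlorophenol, had lower mean signal. None of these directions changed under another scaling between arrays.

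The xylXY signal fell by 1.82 on the log2 scale (SE 0.32, limma adjusted p 0.0128), which is 3.53-fold lower, with every pH 8.45 array below every pH 8.15 array. Its mean log2 signal was 14.70 ± 0.57 at pH 8.15, 13.78 ± 0.19 at pH 7.85 and 12.88 ± 0.15 at pH 8.45. The call was lost without pH 8.45 replicate 2 (adjusted p 0.0619) or replicate 3 (0.0533), after quantile normalization (0.0689) and with only the 6 arrays compared in the fit (0.0578), and over all alternatives the limma adjusted p ran from 0.00315 to 0.0689. The family has 9 tested probes, of which 7 were lower at pH 8.45. One probe, designed on *Ralstonia solanacearum*, held 68.6% of the family signal at pH 8.15 and 37.4% at pH 8.45, with signals of 16367, 34897 and 10164 on the pH 8.15 arrays and 1773, 4575 and 2306 on the pH 8.45 arrays.

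The 11 families next in order of p were also without overlap between the arrays and did not pass in limma. The log2 difference was 2.11 for xylL (SE 0.58, adjusted p 0.139), 1.49 for SoxV (SE 0.36, adjusted p 0.132), 1.11 for the fungal chitin deacetylase (adjusted p 0.162) and 0.90 for pme_Cdeg (adjusted p 0.159). It was 0.81 for nitro, a family of organic remediation (adjusted p 0.162), 0.51 for pme and 0.44 for ara (both adjusted p 0.165). For nifH it was 0.43 (SE 0.12, adjusted p 0.139). The lower families were inulinase at -1.18, the fungal glucose oxidase at -0.93 and pcpB at -0.85, with adjusted p of 0.139, 0.159 and 0.165. In all, limma called 1 family of 259 and 0 of 23038 probes. At an unadjusted p under 0.05 there were 40 families (13 higher, 27 lower, 12.95 expected by chance) and 3357 probes (483 higher, 2874 lower, 1152 expected). The 3357 ran from 1712 to 3828 with 1 array left out and from 1200 to 5363 over the other alternatives. Arrays did not overlap in 65 families (25.1%, against 10% by chance).

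**Figure D3:**
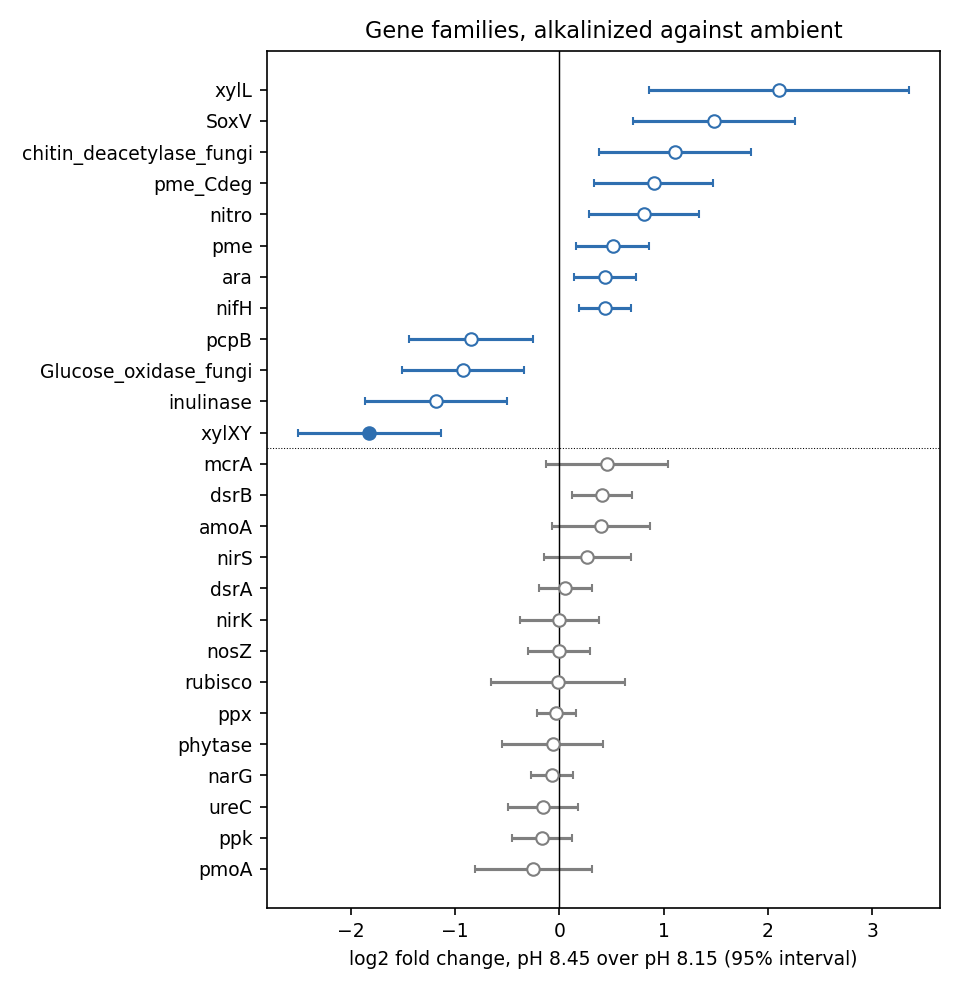
Log2 fold change of gene family signal at pH 8.45 over pH 8.15 (x axis, with 95% intervals from 3 arrays per treatment) for the 12 families with the smallest p (blue) and the families fixed in advance (grey), with a filled point where the family passed. Only xylXY passed, at -1.82, and of the grey families the signs of narG, nirK, nosZ, rubisco, ppk, ppx, phytase, ureC, pmoA and dsrA change under at least 1 other scaling.

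The families fixed in advance for this comparison did not pass over all families. The sulfite reduction gene dsrB differed by 0.41 on the log2 scale, mcrA by 0.46, amoA by 0.40 and nirS by 0.27, each with the same sign under every scaling. As a mean of probe log2 values mcrA (-0.34, 63 of 93 probes lower), amoA (-0.35, 16 of 23) and nirS (-0.37, 165 of 246) had the opposite sign. With 1 array left out, nirS went down to 0.035 and mcrA ran from 0.28 to 0.82. The others were 0.06 for dsrA, 0.00 for nirK, -0.00 for nosZ, -0.07 for narG, -0.01 for rubisco, -0.16 for ureC, -0.25 for pmoA, -0.17 for ppk, -0.03 for ppx and -0.07 for phytase. Median scaling over the probes detected on all 9 arrays turned each negative one of these positive, and mean scaling turned dsrA and nirK negative. Quantile normalization turned nirK negative and nosZ and phytase positive, and total scaling turned nirK negative. With 1 array left out, rubisco ran from -0.51 to 0.27, phytase from -0.30 to 0.16, pmoA from -0.45 to -0.069 and ureC from -0.28 to -0.035, and dsrA, nirK, nosZ and ppx also changed sign. With undetected values left missing, pmoA turned to 0.10.

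Higher sums went with lower signal of most probes in several families. The summed nifH signal was higher at pH 8.45 while 330 of its 467 probes (70.7%) had lower signal and the mean log2 difference over its probes was -0.34. The same held for dsrB, with 258 of 358 probes lower and a mean of -0.43, for ara, with 243 of 339 lower and a mean of -0.42, and for pme, with a mean of -0.39. It also held for pme_Cdeg (-0.27, 28 of 35 probes lower), nitro (-0.33, 40 of 55) and the fungal chitin deacetylase (-0.23, 10 of 15). The means of xylL (0.12, with 11 of 15 probes lower) and SoxV (0.21, with 4 of 7 lower) stayed above 0. Across the 259 families, 177 had a lower sum at pH 8.45 and 251 a lower mean of probe log2 values, and 74 had a higher sum with a lower mean. With the mean of log2 values as the family value, limma called 93 families, all lower. The median difference over all tested probes was -0.48, over all families -0.17 and over probes detected on all 9 arrays -0.38. With undetected values at a common floor the median over all tested probes was -0.26. These medians depend on the scaling as well. The median over families was -0.10 after quantile normalization, -0.39 after mean scaling and 0.18 after median scaling, and that over probes was -0.20, -0.70 and -0.13. Of the probes at an unadjusted p under 0.05, 14.4% were higher at pH 8.45 with deposited values, 25.2% after quantile normalization, 6.28% after mean scaling and 45.8% after median scaling.

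Among the fixed lists, aromatic carbon and lignin degradation had lower signal at pH 8.45 in every family with deposited values, where 177 of all 259 families were lower. The 10 aromatic families differed by log2 -0.87 to -0.10 with a median of -0.41 and a smallest p of 0.113 when adjusted over the list alone. All 7 lignin families differed by -0.76 to -0.07, also with a median of -0.41. After median scaling 4 of the 10 aromatic and 3 of the 7 lignin families were higher, and after quantile normalization 1 of the 10 and 0 of the 7. The 3 families of assimilatory nitrogen reduction had lower signal, of which 1 was higher after median scaling. The 4 families of the chitin list had higher signal by 0.15 or less, and each had lower signal after mean scaling. Carbon fixation (7 higher and 5 lower of 12), denitrification (3 and 2 of 5), sulfate and sulfite reduction (3 and 2 of 5) and sulfur oxidation (1 and 6 of 7, with SoxV the higher one) were mixed with deposited values. After median scaling 10 of the 12, 5 of the 5, 5 of the 5 and 6 of the 7 had higher signal. In each of these lists 0 families passed over all families. Adjusted over the list alone, SoxV (limma adjusted p 0.00713), dsrB (0.0437), ara (0.0260) and the pectin families pme and pme_Cdeg (smallest 0.0186) had higher signal. So adjusted, the methane monooxygenase gene mmoX had lower signal (log2 -0.82, adjusted p 0.0334). The median of its list, which holds mmoX and pmoA, went from -0.53 to -0.28 after quantile normalization and -0.18 after median scaling. The nitrogen fixation and mercury lists have 1 tested family each, so their limma p of 0.00219 for nifH (higher) and 0.0137 for the organomercury lyase gene merB (log2 -0.66) is unadjusted. The merB difference was -0.40 after quantile normalization and -0.31 after median scaling. DMSP degradation had 1 tested family, dmdA, with a log2 difference of 0.41 that did not pass.

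Over the probes of each list, camera called 0 of 26 lists in this comparison, with 0 at an unadjusted p under 0.05, and fry called 0, with 17 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0647. All 26 list medians were below 0, from -0.63 to -0.07, and 24 of the 26 after median scaling. Mean, median and fry had the same sign in each list, while the camera direction, which is relative to all other probes, was up in 16. Of 80 subcategories given with the array, camera called 0 (2 at an unadjusted p under 0.05), and fry called 1 with 53 at an unadjusted p under 0.05. That subcategory was the 3-hydroxypropionate bicycle of carbon fixation, with 16 probes, a median log2 difference of -0.56 and an adjusted p of 0.0459. With the camera correlation estimated, 0 lists and 0 subcategories were called in any comparison.

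Probes were also summed by the phylum of the organism they were designed on. Limma tested these sums on the log2 scale, and the percentages in this paragraph were not tested themselves. Taxa were taken as sums only. The mean of probe log2 values, which changed the sign of many families, was not computed for them. Actinobacteria, filamentous and other high-GC bacteria, were the only taxon called over the 3 treatments (limma F test, adjusted p 0.0351, 7 of 31 taxa at an unadjusted p under 0.05). Their probes held 19.7% ± 1.7 of the tested signal at pH 7.85, 21.3% ± 0.2 at pH 8.15 and 17.4% ± 0.9 at pH 8.45. Their signal fell by 0.28 on the log2 scale (SE 0.07, limma adjusted p 0.00924) from pH 8.15 to pH 8.45 in 3912 probes, with every pH 8.45 array below every pH 8.15 array (exact p 0.1), but the difference was 0.068 and uncalled after median scaling. That scaling multiplies each array by 1 factor and so raises all taxa at pH 8.45 alike. It leaves the share of Actinobacteria unchanged, whose log2 difference was -0.29. Mean scaling also multiplies each array by 1 factor and leaves the share of every taxon unchanged. The call was lost without pH 8.15 replicate 1 (adjusted p 0.0523), pH 8.15 replicate 2 (0.0592) or pH 8.45 replicate 2 (0.0691), after mean scaling (log2 -0.50, adjusted p 0.508) and with undetected values left missing (log2 -0.13, adjusted p 0.641), and the limma adjusted p ran from 0.00126 to 0.641 over all alternatives. Firmicutes, spore formers and relatives, held 5.82% ± 0.53, 5.23% ± 0.08 and 6.43% ± 0.57 (log2 difference 0.30 from pH 8.15 to pH 8.45, adjusted p 0.0555), without overlap between the arrays. Firmicutes passed under total scaling (limma adjusted p 0.0284), median scaling (log2 0.65, adjusted p 0.00745), the replicate block (0.0394), the common detection limit (0.0404) and no detection filter (0.0465). They also passed with only probes detected on all 9 arrays (0.0234) or on all 3 arrays of a group (0.0218), but not after mean scaling (log2 0.08, adjusted p 0.936) or with undetected values left missing (log2 0.50, adjusted p 0.230). Nor did they pass after quantile normalization (0.0528), with the stricter detection limit (0.0596) or with the common floor (0.0555). With 1 array left out the adjusted p ran from 0.0145 to 0.337, the highest without pH 8.15 replicate 3. Proteobacteria held 40.4%, 40.4% and 40.7%. By domain, Bacteria held 88.9%, 88.8% and 87.9%, Eukaryota 8.11%, 8.10% and 8.40%, and Archaea 2.09% ± 0.26, 2.26% ± 0.12 and 2.57% ± 0.14. Gene categories had 0 limma calls over the 3 treatments, with 1 of 9 at an unadjusted p under 0.05. Carbon cycling genes held 44.5%, 44.0% and 43.7% of the signal, phosphorus genes 4.46%, 4.63% and 4.41%, nitrogen genes 11.2%, 11.1% and 11.8%, and sulfur genes 9.02%, 8.57% and 9.05%.

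**Figure D4:**
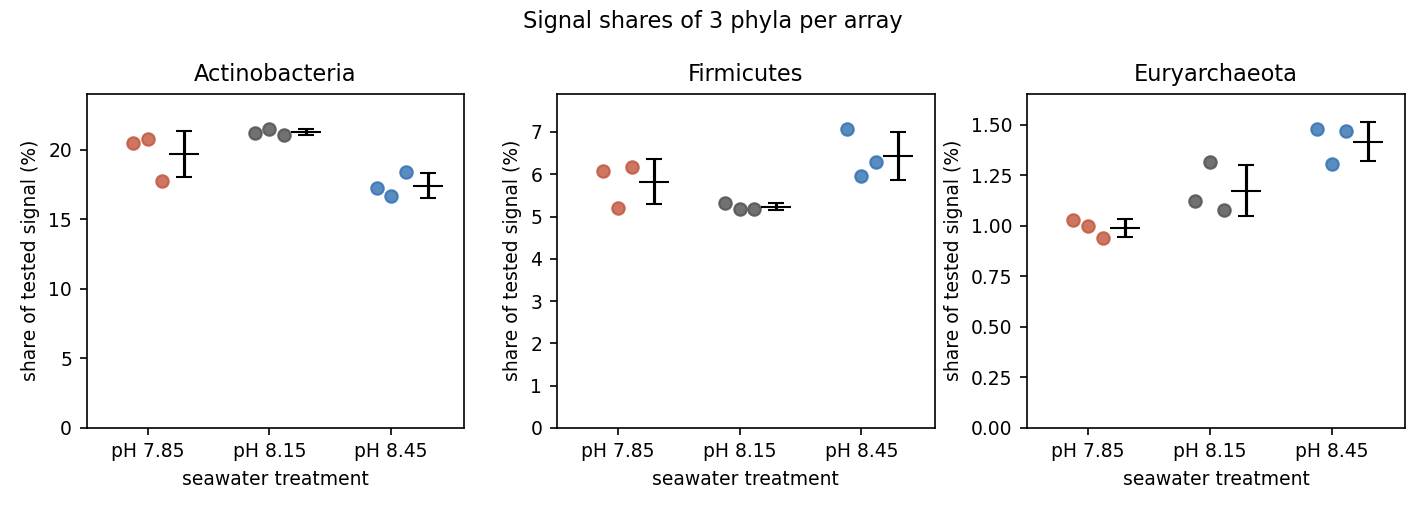
Percentage of the tested signal held by probes designed on Actinobacteria, Firmicutes and Euryarchaeota for each array (points), with the mean and SD of the 3 arrays of each treatment. The 3 pH 8.45 arrays lie below the 3 pH 8.15 arrays for Actinobacteria. Median scaling, 1 factor per array, leaves these shares unchanged and raises the summed signal of all taxa at pH 8.45 alike, which turns the log2 difference in Actinobacteria sums from -0.28 to 0.068.

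Acidified seawater was compared with alkalinized seawater as the ends of the pH range. Euryarchaeota, the phylum that holds the methanogens, passed with lower summed signal at pH 7.85 than at pH 8.45, and no gene family passed. The carbon fixation enzyme phosphoenolpyruvate carboxylase (PEPC), the lignin family glx, endoglucanase, xylXY, the fungal glucose oxidase and the elongation factor marker of Stramenopiles had higher mean signal at pH 7.85. Nitrogen fixation (nifH), sulfite reduction (dsrB), nitrate reductase and the hydrocarbon families xylL, bphB and cpnA had lower mean signal. Each of these signs held under every scaling, but not each one held when a family was taken as the mean of its probes' log2 values. So taken, nifH differed by 0.30 (338 of 467 probes higher), dsrB by 0.32 (265 of 358), nitrate reductase by 0.28 (50 of 72) and xylL by 0.18 (12 of 15). With only the probes detected on all 9 arrays, cpnA turned to 0.45. Of the 259 families, 82 had a lower sum and a higher mean of log2 values at pH 7.85.

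Euryarchaeota probes held 0.987% ± 0.044 of the signal at pH 7.85, 1.17% ± 0.13 at pH 8.15 and 1.42% ± 0.10 at pH 8.45. Their signal was lower by a log2 difference of -0.52 (SE 0.14, limma adjusted p 0.0319) at pH 7.85 than at pH 8.45, with no overlap (exact p 0.1). That call was lost without pH 7.85 replicate 3 (adjusted p 0.0574), pH 8.15 replicate 1 (0.0519), pH 8.45 replicate 1 (0.0729) or pH 8.45 replicate 3 (0.142), after mean scaling (log2 -0.50, adjusted p 0.559) and with undetected values left missing (log2 -0.52, adjusted p 0.381), and the limma adjusted p ran from 0.00187 to 0.0391 over the other alternatives. Mean scaling leaves the Euryarchaeota share unchanged, since it multiplies each array by 1 factor. The Euryarchaeota call was the only one among 31 taxa, with 6 at an unadjusted p under 0.05. It rests on summed signal, and whether most Euryarchaeota probes were lower was not examined. The log2 difference of PEPC was 1.19 (SE 0.33), that of nifH -0.40 (SE 0.12) and that of dsrB -0.44 (SE 0.14). It was 1.06 for glx, 0.61 for endoglucanase, 0.90 for xylXY, 0.73 for the fungal glucose oxidase, 0.95 for the Stramenopiles marker, -0.61 for nitrate reductase, -1.75 for xylL, -1.59 for bphB and -1.02 for cpnA. With 1 array left out, glx ran from 0.57 (without pH 7.85 replicate 3) to 1.32, the Stramenopiles marker from 0.61 to 1.07, endoglucanase from 0.43 to 0.81, xylL from -2.51 to -1.15 and cpnA from -1.39 to -0.70. The limma adjusted p was 0.355 for all 12 families. Limma called 0 of 259 families, with 26 at an unadjusted p under 0.05 (13 higher, 13 lower), and 0 of 23038 probes, with 1607 at an unadjusted p under 0.05 (1297 higher, 310 lower). The 1607 ran from 1078 to 1851 with 1 array left out and from 753 to 1770 over the other alternatives. Of those probes 80.7% were higher at pH 7.85 with deposited values, 50.6% after quantile normalization and 44.8% after median scaling. Arrays did not overlap in 35 families (13.5%, against 10% by chance).

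The lignin list had higher signal at pH 7.85 in all 7 families, by 0.21 to 1.06 on the log2 scale, of which 3 were lower after median scaling. Of all 259 families, 171 had higher signal with deposited values. In the lignin list 0 families passed over all families, and its smallest limma p adjusted over the list alone was 0.0786. Adjusted over the list alone, dsrB had lower summed signal at pH 7.85 (limma adjusted p 0.0298). The nitrogen fixation and methane production lists have 1 tested family each, nifH and the methanogenesis gene mcrA (log2 -0.71), so their limma p of 0.00406 and 0.0215 is unadjusted. The mcrA difference ran from -1.06 to -0.53 with 1 array left out. As a mean of probe log2 values mcrA was higher by 0.25, with 67 of 93 probes higher, and nifH and dsrB were higher as well. Camera called 0 of 26 lists and fry 0, with 0 and 6 at an unadjusted p under 0.05. All 26 list medians were above 0, from 0.18 to 0.54, and 3 of them were below 0 after quantile normalization and 3 after median scaling. Over the 3 pH levels, the limma F test called 0 families, with 29 at an unadjusted p under 0.05 and xylXY nearest (adjusted p 0.0531). A linear trend with pH gave 0 calls, with 22 families at an unadjusted p under 0.05 (9 with positive and 13 with negative slopes) and a smallest adjusted p of 0.390. The family with the smallest p, PEPC, had a slope of -1.99 per pH unit on the log2 scale and did not pass.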

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

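The common floor, the common detection limit, mean scaling, total scaling and the other numbers of brightest probes were chosen only after the data had been seen, and the other alternatives were fixed earlier. For the named families and taxa there were 3132 alternative values. Of these, 2853 kept their direction and their side of the threshold, 221 were uncalled with the opposite sign, 40 newly passed, 15 no longer passed and 3 were reversed. The comparison of pH 7.85 with pH 8.15 had 0 family and 0 probe calls in limma under each alternative, with the main counts at an unadjusted p under 0.05 of 3 and 781. The 781 ran from 215 to 1475, and from 575 to 1281 with 1 array left out. The Shannon index lost its exact p under 0.05 after quantile normalization and kept it under the other alternatives. Several of those could not change it. Median, mean and total scaling multiply each array by 1 factor, which leaves the index as it was. A common floor, undetected values left missing and no detection filter also leave it as it was. The exact p of the share in the brightest probes was 0.0107 to 0.0357 with 50 or 200 probes in place of 100. Where no cause is given below, the cause was not tested.

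Quantile normalization gave 0 families at pH 8.45 against pH 8.15 and 2 taxa over the 3 groups. By construction it equalises the distributions of the probes detected on all 9 arrays. The other probes were adjusted along with them, and their number still differed between arrays. Under it the exact p of the Shannon index became 0.454 and that of the inverse Simpson index 0.496. Median scaling over the probes detected on all 9 arrays multiplies each array by 1 factor and raised pH 8.45, which gave 7 families (6 higher) in that comparison, 8 categories, 8 taxa and a reversed log2 difference for Actinobacteria, 0.068 (uncalled), through that common factor, which leaves their share difference at -0.29. Mean scaling gave 2 families (1 higher) and 10 probes (2 higher) at pH 8.45 against pH 8.15, 2 families in the F test and 1 in the trend. Total scaling gave 1 family in the F test and 2 taxa.

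Without a detection filter there were 9 probe calls (6 higher) at pH 8.45 against pH 8.15 and 3 taxa. With only the probes detected on all 9 arrays there were 0 families, where fewer families and probes were tested. Since fewer than 5 xylXY probes remained, xylXY was not among the tested families there. The same filter gave 3 probes (2 higher) and an exact p of 0.0643 for the inverse Simpson index. The differences in detected probes were 0 in all 3 comparisons by construction. With probes detected on all 3 arrays of a group there were 3 probes (1 higher), 1 family in the F test and 0 taxa. With undetected values left missing there were 29 probes (16 higher) at pH 8.45 against pH 8.15, 3 probes (1 higher) at pH 7.85 against pH 8.45 and 0 taxa, against 1 before. The stricter detection limit gave 13 probes (7 higher) and an exact p of 0.0571 for the inverse Simpson index. The common floor gave 20 probes (5 higher), and the common detection limit 6 probes (3 higher) and 1 family in the F test.

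With the mean of probe log2 values as the family value, which gives dim probes the same weight as bright ones, there were 93 families (0 higher) at pH 8.45 against pH 8.15, 5 (5 higher) at pH 7.85 against pH 8.45, 18 in the F test and 8 in the trend (0 with positive slopes). Under it acetylglucosaminidase and nirK were reversed, at -0.46 and -0.51 against 0.15 and 0.00 before, and nifH turned to -0.34 uncalled. Robust limma gave 1 family in the F test. With only the groups compared in the fit there were 0 families at pH 8.45 against pH 8.15, from fewer arrays, and 5 probes (1 higher) at pH 7.85 against pH 8.45. Fry in place of camera gave 1 subcategory at pH 8.45 against pH 8.15, a test that does not compare a set with other probes.

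The replicate numbers name separate tanks, and the labels give no shared origin for them. Arrays of the same number had correlated deviations over 0.1 in 3 of 9 pairs (-0.19 to 0.16, against -0.25 to 0.27 for different numbers), and 4 of 9 arrays were closest to their own number, so the numbers were not taken to pair the arrays. With the replicate block, 3 families (2 higher) and 6 probes (4 higher) were called at pH 8.45 against pH 8.15, 3 families in the F test and 3 taxa, and the block changed no other count of calls.

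With each array left out in turn, the counts at pH 8.45 against pH 8.15 ran from 0 to 3 families and from 0 to 34 probes, and those at pH 7.85 against pH 8.45 from 0 to 1 families and 0 to 12 probes. Both highest probe counts came without pH 8.45 replicate 1, and the 0 families without pH 8.45 replicate 2 or 3. The F test ran from 0 to 1 families, subcategories in either comparison with pH 8.45 from 0 to 1, categories from 0 to 1 and taxa from 0 to 5. The 5 taxa came without pH 7.85 replicate 2. Taxon counts were 0 without any 1 of the pH 8.15 arrays or without pH 8.45 replicate 2. The exact p of the inverse Simpson index ran from 0.00357 to 0.114, and the difference in detected probes between pH 7.85 and pH 8.45 from -1731 to 1163. Values as deposited are the values reported, so that alternative added nothing. A batch block was not run because no batch is given, and camera and PERMANOVA were not run with missing values. What signal over background would limit cannot be given, since background values were not used here.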

Other observations

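The tests of signal by genus were chosen only after the results by phylum were seen, and the 3 patterns weighed here were found in the data, with the predictions for each test written before its own value was computed.

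Signal summed by genus was tested for 415 genera with at least 10 tested probes. Limma called 4 at pH 8.45 against pH 8.15, with 87 at an unadjusted p under 0.05, each without overlap between the arrays. The limma F test over the 3 groups called 0 genera (smallest adjusted p 0.0943), and each of the other comparisons called 0. Streptomyces, soil and marine Actinobacteria, had lower signal (log2 -0.48, SE 0.09, 685 probes, 4.47% of the signal at pH 8.15 and 3.18% at pH 8.45), as did Spirosoma (-1.57), while Salinisphaera, marine Proteobacteria, had higher signal (1.19), each with an adjusted p of 0.0327. The fungus Moniliophthora had higher signal too (1.74, adjusted p 0.0382). Vibrio, which includes coral pathogens, held 1.05% ± 0.10 at pH 8.15 and 1.72% ± 0.30 at pH 8.45 (log2 0.71, limma adjusted p 0.0957) and did not pass. The directions of genera were not examined under other scalings or as means of probe log2 values.

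The median probe signal was lower at pH 8.45 than at pH 8.15. The tables argue against undetected values at the floor of each array as the whole cause, since the median log2 difference over the probes detected on all 9 arrays was -0.38 and negative in 9 of 9 pairs of arrays (-0.54 to -0.25). Its size depends on the floor, since with a common floor the median over all tested probes was -0.26 against -0.48. They also argue against a single array, since with any 1 left out the median stayed between -0.51 and -0.39. What stays open is a few bright probes taking more of an array total that was set equal: the 100 brightest held 7.46 percentage points more at pH 8.45, and the lowest such array lay above the highest at pH 8.15. That is consistent with a scaling to equal totals by the submitters, which is not recorded, and also with a community dominated by fewer gene variants at high pH, a biological explanation that was not tested.

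The signal of xylXY was lower at pH 8.45. The 20 families nearest in mean signal had a median log2 difference of -0.49 (SD 0.49), which passed the bound set for it only narrowly. Of these families 0 of 20 lay at or below the -1.82 of xylXY. That count was favoured by the choice of xylXY as the only family called. These values therefore do not decide on a loss common to dim families. A single array is argued against, since the xylXY difference stayed at -1.52 or lower with 1 array left out. Without its brightest probe the difference was -0.70 (SE 0.28, exact p 0.1), between the bounds set for the 2 outcomes. With the brightest probe counted, 7 of 9 probes were lower, where 72.5% of all tested probes were lower. A change of the family and a change at 1 probe therefore cannot be told apart with so few probes. Seawater pH may act on a bacterium that carries that gene variant, which was not tested.

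Actinobacteria had lower signal at pH 8.45. Without the Streptomyces probes the log2 difference was -0.23 (SE 0.07, exact p 0.1), so the lower signal was not confined to that genus. The predictions for Actinobacteria were written after the results by phylum and genus had been seen. Those results largely fix the value without Streptomyces, so its bound was not an independent test. GC content stays open: the ratio of high-GC to low-GC Proteobacteria genera differed by -0.18 (exact p 0.2) in the same direction, from 0.03 for the high-GC and 0.20 for the low-GC genera. A few bright probes stay open too, since the difference in share was -0.13 (exact p 0.1) without the 100 brightest probes of each array, against -0.29 with them. Without the 50 brightest it was -0.18, beyond the bound for arguing against this explanation, and without the 200 brightest it was -0.10. Neither GC content nor a few bright probes can be told apart from a response of Actinobacteria to pH. The GC value and the value without the 100 brightest lie between the bounds set before they were computed. In addition, 3 arrays per group allow no smaller exact p than 0.1.

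Other splits of the arrays were counted for each result fitted across many families or probes. For each pair of groups the 6 arrays have 10 splits, too few for a share under 0.05. At pH 8.45 against pH 8.15 there was 1 family call, and 2 of the 10 splits gave as many, the highest other giving 2. The probes at an unadjusted p under 0.05 numbered 3357, with 1 of 10 splits as large and 1570 in the highest other. At pH 7.85 against pH 8.15 they numbered 781, with 7 of 10 splits as large and 2311 in the highest other. At pH 7.85 against pH 8.45 they numbered 1607, with 3 of 10 splits as large and 2208 in the highest other. In both comparisons with pH 7.85 a split other than the real one had more probes than the treatments. Among 10 splits this is common without any treatment effect, so no cause can be read from it. Where limma called 0 families or probes, or camera 0 lists or subcategories, any split gives as many, so splits cannot test these counts. The highest other counts there were 2 families and 6 probes at pH 7.85 against pH 8.15, 1 probe at pH 8.45 against pH 8.15, 0 families and 8 probes at pH 7.85 against pH 8.45, and 0 lists and 0 subcategories in each comparison.

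For the tests over 3 groups 100 splits were drawn, the real one included. At an unadjusted p under 0.05 the F test had 29 families, which 6 of the 100 reached (highest other 45), and taxa had 1 call, which 5 of the 100 reached (highest other 2). Chance is not excluded for these counts. The F test (highest other 3), the trend (highest other 3) and the categories (highest other 2) had 0 calls, which any split reaches, so splits cannot test them.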
